A study of Mus musculus with 6 samples.

How the data were processed

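CCE mouse embryonic stem cells, grown without feeder cells in medium with serum and leukemia inhibitory factor (LIF), were transfected with plasmids expressing a short hairpin RNA (shRNA) and selected in puromycin for 4 days, starting 18 h after transfection. One of 3 hairpins was used: Prmt6 shRNA1, Prmt6 shRNA2, or an shRNA against GFP as the control. Each group had 2 arrays, 6 in all. Biotin-labelled cRNA was made from total RNA and hybridized to Illumina mouse bead arrays. The labels do not say whether the replicates were separate cultures, so each p-value measures the spread between these samples.

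The deposited table without normalization gave, for each array and probe, a mean bead intensity on a linear scale, from which the background had already been subtracted by the authors. Beside each intensity stood a detection score per the file headers, from 0 to 1, read here as 1 minus the detection p-value because it rose with the signal on every array. The authors also deposited processed values on a log2 scale, made with lumi per the submitters' processing notes, which give no version, transformation or normalization method. Each processed column ranked the probes as the intensity column of the same sample did. No intensity column was identical to another. The array build is not named in the sources used here.

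The intensities were background-corrected and quantile-normalized with neqc in limma 3.58.1 under R 4.3.3, which used the detection p-values and an offset of 16. A probe was kept when its detection p was under 0.01 on at least 2 of the 6 arrays. Names on the array were matched to current mouse symbols and their synonyms in a RefSeq gene table (assembly GRCm38.p6, used for names only). Of 46643 probes, 34387 had a matched symbol. The filter kept 9138 probes, of which 8170 had a symbol. The brightest kept probe stood for each gene, which left 6539 genes. The probe IDs fell into 2 series, referred to here as first and second, with 24613 and 22030 probes. The second series supplied 1133 of the genes tested.

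A group-means model was fitted to all 6 arrays with lmFit and eBayes in limma (prior degrees of freedom 2.81, residual degrees of freedom 3). P-values are two-sided, adjusted over all genes tested by the method of Benjamini and Hochberg, and called below 0.05. The contrasts were each Prmt6 hairpin against the GFP hairpin, the average of both hairpins against it (the main comparison), and Prmt6 shRNA2 minus Prmt6 shRNA1. Errors after ± are limma standard errors unless marked SD. An exact permutation test cannot go below p = 0.133 for 4 arrays against 2 or p = 0.333 for 2 against 2, so limma's moderated test was used. For a gene detected on no array of one group, the fold is given as a lower limit: the mean log2 value of the brighter group was set against the mean of, for each array of the dim group, the higher of its own value and the lowest detected signal on that array.

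Before the data were examined, the groups, the contrasts, the alternatives, 28 gene lists and the rule for naming genes were fixed. The rule took Prmt6 first. In the main comparison it took up to 12 of the largest rises and 12 of the largest falls among called genes with the same sign with each hairpin and all 4 Prmt6 shRNA arrays on one side of both GFP shRNA arrays. In the other contrasts it took the 5 largest rises and 5 largest falls. It also took up to 4 called members of each list, and 13 pluripotency, cell cycle and lineage genes whatever their result. Symbols of uncharacterised loci were passed over. Any other gene named was chosen after its values were seen.

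The lists covered core pluripotency, naive pluripotency, formative and primed epiblast, endoderm, primitive streak and mesoderm, neuroectoderm, trophectoderm, Hox genes, p53 targets, cyclin-dependent kinase inhibitors and G1 regulators, S and G2/M proliferation, the interferon and double-stranded RNA response, protein arginine methyltransferases, H3K4 methylation, Polycomb, unfolded protein and related stress, the 2-cell-like state, fibroblast and feeder markers, LIF and STAT3 targets, Wnt targets, Nodal, TGF-beta and BMP targets, FGF and ERK targets, cholesterol synthesis, glycolysis and hypoxia, germline genes, imprinted genes, apoptosis, and reference genes. A list was tested when at least 3 members were measured, which held for 24. The test was camera in limma with a preset inter-gene correlation of 0.01, adjusted over the 24 lists of a comparison. It was repeated with the correlation estimated from the data, and fry was added as a description. Unlike camera, fry asks whether a list's members changed at all, not whether they changed more than other genes. In the main comparison fry gave adjusted p from 0.00132 to 0.0405 for the 7 lists that camera called. It gave 0.0117 for imprinted genes, which camera did not call. Adjusted p-values over a list's own members are given as counts adjusted over the list alone.

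The overlap between the hairpins was set beside the number from independent lists and beside 100 simulated sets of unchanged groups that share the control arrays. Because these sets called almost no genes, lists of the observed sizes, made of the genes with the lowest p-values in each direction, were also compared, a choice made after the data were seen. The chain was tested on simulated data, 5 sets with 200 changed genes each. In the first specification the spread of all genes, which already held background noise, was used and that noise was added again, and 1 of 185 genes lowered 4-fold on both hairpins' arrays was called. The specification was then changed once, to mean intensities as the signal and the spread of bright genes. With it, the main comparison called 80.8% of 4-fold rises, 45.8% of 4-fold falls, 1.2% of 2-fold rises and 0.469% of 2-fold falls, and 4 of 42840 unchanged genes. These sets held 8619 to 8816 genes, against 6539 in the data. Their genes varied independently and no array had low second-series signal, so the rates may be too high for the real arrays. In the same sets, camera called a list of raised genes in 5 of 5 and a list of unchanged genes in 1 of 5.

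The alternatives were no background correction, scaling to a common median, another offset, the authors' processed values, other detection filters, every probe or the mean of a gene's probes, a fit to only the groups compared, eBayes with trend and robust options, the replicate number as a block, other thresholds, and leaving out each array in turn. Chosen after seeing the data were the first probe series alone, each series normalized separately, array weights, and combinations of these. A slide block was not run, because slides are not given in the sources used here. The 968 kept probes without a matched symbol were tested apart and enter no count of genes. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15.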

Results

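Transcript levels were measured in CCE mouse embryonic stem cells that expressed one of 3 hairpins for 4 days of puromycin selection. A pair of hairpins targeted Prmt6, an enzyme that adds asymmetric dimethyl groups to arginines and is known for methylating arginine 2 of histone H3. The control hairpin targeted GFP, which these cells are not described as carrying. Each group had 2 arrays. The title of the series places the question in pluripotency and reprogramming, and the comparisons below ask which transcripts changed when Prmt6 was targeted.

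The number of arrays limits the precision of every value. Detected probes ranged from 5782 on Prmt6 shRNA2 replicate 2 to 10928 on Prmt6 shRNA1 replicate 2, or 12.4% to 23.4% of the probes. On Prmt6 shRNA2 replicate 2, 935 second-series probes were detected, against 1302 to 2836 on the other arrays. Across the kept second-series probes the replicates of Prmt6 shRNA2 correlated with r = 0.714, and across the first-series probes with r = 0.971. Over both series, r was 0.973 between the GFP shRNA replicates and 0.959 between the Prmt6 shRNA1 replicates. Some pairs across groups lay above the latter. Prmt6 shRNA1 replicate 2 with GFP shRNA replicate 1 gave 0.966. Prmt6 shRNA1 replicate 1 gave 0.960 with GFP shRNA replicate 2 and 0.970 with Prmt6 shRNA2 replicate 1. All are correlations across probes, which are not independent replicates. The SD of the difference between replicates was 0.39 log2 units with GFP shRNA, 0.48 with Prmt6 shRNA1 and 0.79 with Prmt6 shRNA2. Within Prmt6 shRNA2 it was 0.42 on first-series and 1.42 on second-series probes.

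**Figure D1:**
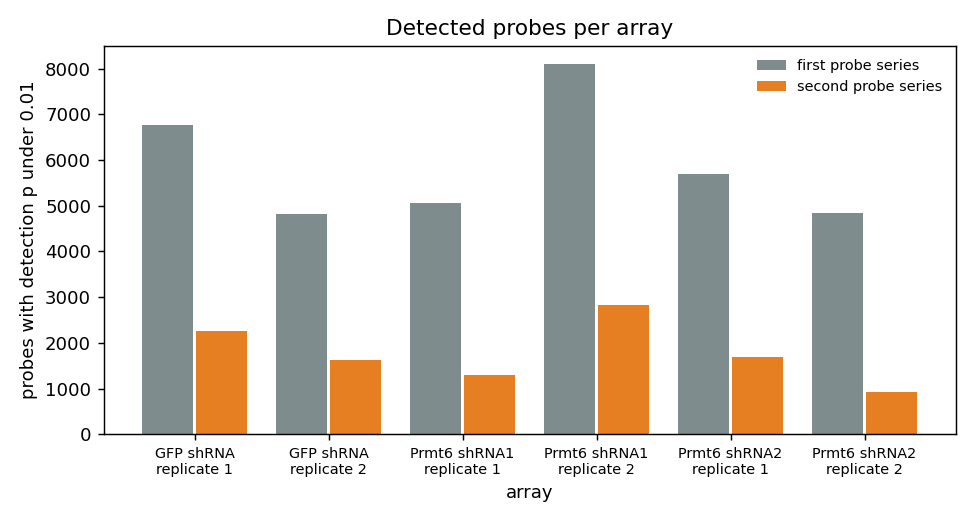
Probes with a detection p under 0.01 on each array (vertical axis, number of probes), in the first series (grey bars) and the second series (orange bars). The second-series bar is lowest on Prmt6 shRNA2 replicate 2, at 935 probes, and highest on Prmt6 shRNA1 replicate 2, at 2836.

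The targeted transcript was lower on all 4 Prmt6 shRNA arrays than on both GFP shRNA arrays, but the difference did not pass the test over all genes. The intensities of the brightest Prmt6 probe were 389.8 and 266.1 with GFP shRNA, 48.3 and 147.6 with Prmt6 shRNA1, and 97.8 and -21.6 with Prmt6 shRNA2. The normalized means were 8.26 ± 0.15, 6.81 ± 0.64 and 6.03 ± 0.69 log2 units (SD, n = 2 each). Prmt6 was detected on both GFP shRNA arrays, on 1 Prmt6 shRNA1 array and on no Prmt6 shRNA2 array. With both hairpins the fitted log2 difference from GFP shRNA was -1.84 ± 0.37, with a lower limit of 1.52-fold (limma adjusted p = 0.082). With Prmt6 shRNA1 alone it was -1.45 ± 0.43, or 2.74-fold (adjusted p = 0.243), and with Prmt6 shRNA2 alone at least 1.40-fold (adjusted p = 0.0904). The remaining Prmt6 level did not differ detectably between the hairpins (adjusted p = 0.486). A further kept probe for the same gene was also lower on all 4 Prmt6 shRNA arrays than on both GFP shRNA arrays. Every kept Prmt6 probe belonged to the second series. Without Prmt6 shRNA2 replicate 1, which leaves the array with low second-series signal alone in its group, the difference passed, at a fitted -2.08 (adjusted p = 0.0267). Without replicate 2 of that group it was -1.65 (adjusted p = 0.149), and without each of the other arrays the adjusted p lay between 0.0949 and 0.438.

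Averaged over both Prmt6 hairpins, the largest rises over GFP shRNA included those of Krt7, Krt18, Krt8, Acta1, Acta2 and Igf2. Krt7, Krt18 and Krt8, intermediate filament proteins of simple epithelia, rose 9.56-fold, 9.05-fold and 6.83-fold (log2 3.26 ± 0.30, 3.18 ± 0.24 and 2.77 ± 0.16; limma adjusted p = 0.0131, 0.0101 and 0.00941). The Krt7 average came mostly from Prmt6 shRNA1, since with Prmt6 shRNA2 alone Krt7 was at 2.32-fold and did not pass (adjusted p = 0.184). Acta1, the actin of skeletal muscle, was detected on no GFP shRNA array and on no Prmt6 shRNA2 array. Its average rise of at least 3.79-fold (limma adjusted p = 0.00941) therefore rests on the signal with Prmt6 shRNA1, and no rise with Prmt6 shRNA2 was established. Acta2, the smooth muscle actin, rose 5.89-fold on its brightest probe (log2 2.56 ± 0.31, adjusted p = 0.0291). Its other kept probe gave 0.71 with both hairpins, 1.12 with Prmt6 shRNA1 and 0.30 with Prmt6 shRNA2, and with every probe tested neither Acta2 probe passed (adjusted p = 0.31, and 0.0586 for the brightest). Acta1 and Acta2 did not pass with Prmt6 shRNA2 alone (adjusted p = 0.0593 and 0.0938). Igf2, an imprinted fetal growth factor, rose 6.10-fold (log2 2.61 ± 0.19, adjusted p = 0.0101).

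Axl, a receptor tyrosine kinase for Gas6, rose at least 2.93-fold (adjusted p = 0.00941). Anxa3, a calcium-dependent phospholipid-binding protein, rose 6.24-fold, and Plaur, the urokinase receptor, rose 5.85-fold (adjusted p = 0.0101 and 0.0102). Cryab, a small heat shock protein, rose 5.57-fold and Nipal4, a membrane protein needed for the skin barrier, 5.06-fold (adjusted p = 0.0186 and 0.0212). Nppb, which encodes brain natriuretic peptide, rose at least 1.52-fold (adjusted p = 0.0101).

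The falls were fewer and smaller, and in the simulated sets of changed genes the chain also called falls less often than rises. Tcf15, a bHLH factor linked to exit from naive pluripotency and to somite formation, fell 2.45-fold (log2 -1.29 ± 0.19, adjusted p = 0.0435). Eras, a constitutively active Ras protein of embryonic stem cells, fell 2.44-fold (log2 -1.29 ± 0.19, adjusted p = 0.0444). Ezh2, the methyltransferase of Polycomb repressive complex 2, fell 1.90-fold (log2 -0.92 ± 0.14, adjusted p = 0.0461). Sfrp1, a secreted Wnt inhibitor, fell at least 1.25-fold, Gli2, a Hedgehog transcription factor, 2.33-fold, and Lck, a Src-family kinase, 2.18-fold (adjusted p = 0.0411, 0.0444 and 0.0325). Sall3, a zinc-finger factor, fell at least 1.52-fold, Catsperz, a subunit of a sperm calcium channel, at least 1.75-fold, Robo4, a Roundabout receptor, 2.15-fold, Nupr1, a stress-response regulator, 2.09-fold, and Aard 1.98-fold (adjusted p from 0.0386 to 0.049). Sfrp1, Sall3 and Catsperz were detected on no Prmt6 shRNA2 array, and Sall3 and Gli2 were measured by second-series probes.

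**Figure D2:**
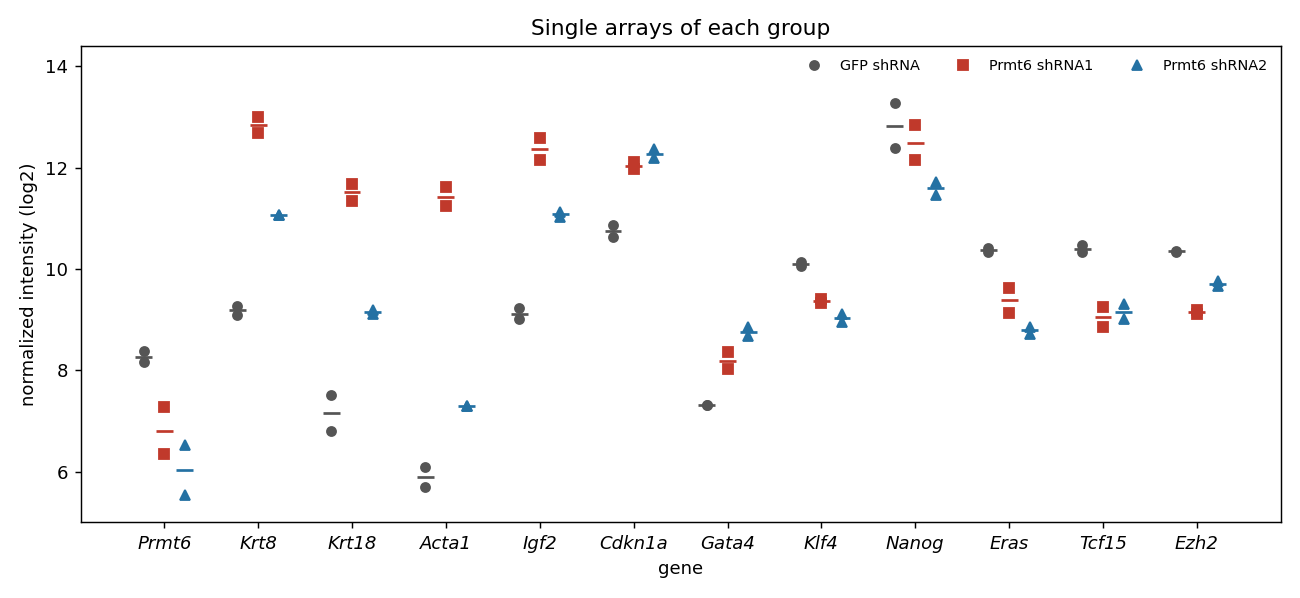
Normalized intensity (vertical axis, log2) of 12 genes on each array, with GFP shRNA as grey circles, Prmt6 shRNA1 as red squares and Prmt6 shRNA2 as blue triangles; short lines mark group means. Prmt6 had group means of 8.26, 6.81 and 6.03 in that order, and Krt8 and Igf2 lay above both GFP shRNA arrays on all 4 Prmt6 shRNA arrays.

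In all, 109 of the 6539 genes passed the limma test, 98 higher and 11 lower, and 952 had an unadjusted p under 0.05. For 106 of the 109, all 4 Prmt6 shRNA arrays lay beyond both GFP shRNA arrays on the same side. Such separation was seen for 24.6% of all genes tested, where chance alone gives 13.3%. By fitted values, 103 of the 109 changed at least 2-fold. These include genes whose lower limits, given above, are under 2-fold, such as Nppb and Sfrp1. The count changed strongly as single arrays were left out. Each such fit leaves 1 array alone in its group and fewer residual degrees of freedom, so a lost call need not come from that array's values. The log2 changes of Krt8 and Igf2 stayed at 2.68 to 2.86 and 2.50 to 2.72 in these fits. Those of Krt7 and Acta2 moved more, from 2.82 to 3.69 and from 2.03 to 3.09. With the first-series probes alone, an alternative chosen after seeing the data, the count was 273, with 216 higher and 57 lower. It held 102 of the 109 genes. Falls were also a larger share with detection on all 6 arrays (243 higher, 59 lower).

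Of the trophectoderm list, markers of the outer layer of the blastocyst, 6 of 9 measured members rose and 3 did not pass, with the same 6 adjusted over the list alone. Besides the keratins, they included Cldn4, a tight junction claudin, at 4.04-fold (adjusted p = 0.0104) and Gata3, chosen after its values were seen, at least 1.10-fold (adjusted p = 0.0291). The transcription factor Cdx2 was at log2 0.47 ± 0.30 and did not pass (adjusted p = 0.549), with 0.22 and 0.74 without GFP shRNA replicate 1 or 2 and 0.26 without Prmt6 shRNA1 replicate 1. The list's median log2 change was 1.77, or 0.47 with members detected on no GFP shRNA array at their lower limits, or at 0 where none lay above 1-fold. Without a filter on dim probes it was 0.52, with the authors' values 1.11 and without background correction 2.79. The list was higher by camera (adjusted p = 3.34e-08), but not with an estimated correlation (adjusted p = 0.139).

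Endoderm genes were higher as a list by camera (adjusted p = 3.34e-08), but not with an estimated correlation (adjusted p = 0.202). All 13 measured members lay above 0, with a median log2 change of 1.00 (0.81 with 1 member not detected with GFP shRNA at its lower limit, and 0.52 without a filter). Gata4, an endoderm transcription factor, rose 2.24-fold (log2 1.16 ± 0.17, adjusted p = 0.0416) and Col4a1, a basement membrane collagen, rose 2.08-fold (log2 1.06 ± 0.16, adjusted p = 0.0457). The other 11 did not pass, among them Sox17 at 1.39 and Gata6 at 0.76, while 10 members were higher adjusted over the list alone.

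No member of the pluripotency lists passed the test over all genes as reported. Of the core pluripotency list, all 14 measured members lay below 0 (median log2 -0.47) and 0 passed by limma, with 2 lower adjusted over the list alone, Gdf3 and Sox2. Pou5f1, which encodes Oct4, was at -0.40 ± 0.20 (adjusted p = 0.433) and Sox2 at -0.72 ± 0.16 (adjusted p = 0.105). Of the naive pluripotency list, 13 of 14 members lay below 0 (median -0.48), 0 passed by limma, and 4 were lower adjusted over the list alone. Klf4 was at -0.90 ± 0.15 (adjusted p = 0.0519), Nanog at -0.79 ± 0.32 on its brightest probe (adjusted p = 0.348), Zfp42 at -0.65 ± 0.18 (adjusted p = 0.184) and Esrrb at -0.36 ± 0.19 (adjusted p = 0.453). The Nanog value was -0.34 without GFP shRNA replicate 1 and -1.22 without GFP shRNA replicate 2. Its other kept probes gave -1.22 and -1.19, and with the mean of its probes Nanog passed, at -1.07 (adjusted p = 0.0435). The other kept probes of Klf4 gave -0.70 and -0.65, that of Sox2 -0.43 and that of Pou5f1 -0.67. Of 24 alternatives, Klf4 passed in 10, Sox2 in 4, Zfp42 in 3 and Nanog in 2, and Pou5f1 and Esrrb in none. Camera called both lists lower, with adjusted p = 3.33e-05 for core and 2.74e-06 for naive pluripotency, and neither with an estimated correlation (adjusted p = 0.139 for each).

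Of the S and G2/M proliferation list, all 22 measured members lay below 0, with a median log2 change of -0.39, or -0.24 without a filter, 0 passed by limma, and 0 passed adjusted over the list alone. The list was lower by camera (adjusted p = 3.34e-08; adjusted p = 0.272 with an estimated correlation). Among p53 targets 1 of 18 rose, Cdkn1a, the cyclin-dependent kinase inhibitor p21, at 2.66-fold (log2 1.41 ± 0.16, adjusted p = 0.0274). The other 17 did not pass, and 4 were higher adjusted over the list alone: Cdkn1a, Mdm2, Plk2 and Polk. The p53 list's median was 0.34 and it was higher by camera (adjusted p = 0.00109; adjusted p = 0.276 with an estimated correlation). In the list of cyclin-dependent kinase inhibitors and G1 regulators, Cdkn1a was the 1 riser of 15, 3 were higher adjusted over the list alone, and the median was 0.01 (camera adjusted p = 0.666). Cdkn1b was not detected on any array.

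Of the neuroectoderm list, 0 of 6 measured members passed by limma and 2, Gbx2 and Stmn2, were lower adjusted over the list alone. Its median was -0.57 and it was lower by camera (adjusted p = 0.0387; adjusted p = 0.276 with an estimated correlation). That call was lost without Prmt6 shRNA1 replicate 2, Prmt6 shRNA2 replicate 1 or Prmt6 shRNA2 replicate 2 (adjusted p = 0.0979, 0.0567 and 0.0507; median -0.34 without the last). It was also lost without a filter on dim probes (adjusted p = 0.157, median -0.006), and with the first-series probes alone (0.0548, or 0.0681 without Prmt6 shRNA2 replicate 2 as well), where the other 6 called lists kept their calls. It was kept with the authors' values, at a median of -0.36, or -0.20 with the first series alone.

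Several lists held called genes without being called themselves. Imprinted genes had 2 risers among 11, Igf2 and the noncoding RNA H19 (at least 1.90-fold, adjusted p = 0.0101), the same count adjusted over the list alone, and a median of 0.23 (camera adjusted p = 0.0983). FGF and ERK targets had 2 risers among 13: Phlda1, a pleckstrin-homology protein, at 3.51-fold, and Dusp4, a MAP kinase phosphatase, at 1.99-fold (adjusted p = 0.0118 and 0.0485); a second-series probe for Dusp4 gave log2 0.47, with -0.41 for Prmt6 shRNA2. Adjusted over the list alone, 4 of them were higher and 1 lower. Their median was -0.21, while the mean was 0.06 and the direction of camera was up (adjusted p = 0.929). Of the Polycomb list 1 of 12 fell, Ezh2, also adjusted over the list alone (median -0.04, camera adjusted p = 0.105). Of glycolysis and hypoxia genes 1 of 17 rose, P4ha2, a collagen prolyl hydroxylase, at 2.15-fold (adjusted p = 0.0435), also adjusted over the list alone (median -0.10, camera adjusted p = 0.645). Of 6 measured fibroblast and feeder markers 1 rose, Acta2, also adjusted over the list alone (median 0.45, camera adjusted p = 0.0612).

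In the remaining lists 0 members passed by limma and camera made no call. Adjusted over the list alone, Prmt6 was lower among 8 arginine methyltransferases and partners (median -0.12, camera adjusted p = 0.382). LIF and STAT3 targets had 1 member higher and 2 lower of 7 adjusted over the list alone (median -0.15, adjusted p = 0.153). Germline genes had 1 of 6 higher (median 0.17), and Nodal, TGF-beta and BMP targets 1 of 4 (median 0.35), both adjusted over the list alone and both with camera adjusted p = 0.382. Apoptosis genes had 2 of 13 higher adjusted over the list alone (median 0.06, adjusted p = 0.724). Of 5 interferon genes 2 were higher adjusted over the list alone, with a median of -0.33, a mean of 0.10 and a downward camera direction (adjusted p = 0.973). Reference genes had 1 of 12 higher adjusted over the list alone, with a median of -0.04, a mean of 0.04 and an upward camera direction (adjusted p = 0.873). H3K4 methylation genes (14 measured, median -0.04, adjusted p = 0.186), formative and primed epiblast genes (5 measured, 0.17, 0.637), and unfolded protein and stress genes (13 measured, 0.12, 0.724) had 0 members past the limma threshold adjusted over the list alone. Cholesterol synthesis genes (15 measured) had none either, with a median of -0.05, a mean of 0.01 and a camera adjusted p of 0.832. Too few members were measured to test primitive streak and mesoderm (2 of 23), Hox genes (2 of 35), the 2-cell-like state (1 of 17) and Wnt targets (1 of 14). Fgf5 and Tbxt were not detected on any array.

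**Figure D3:**
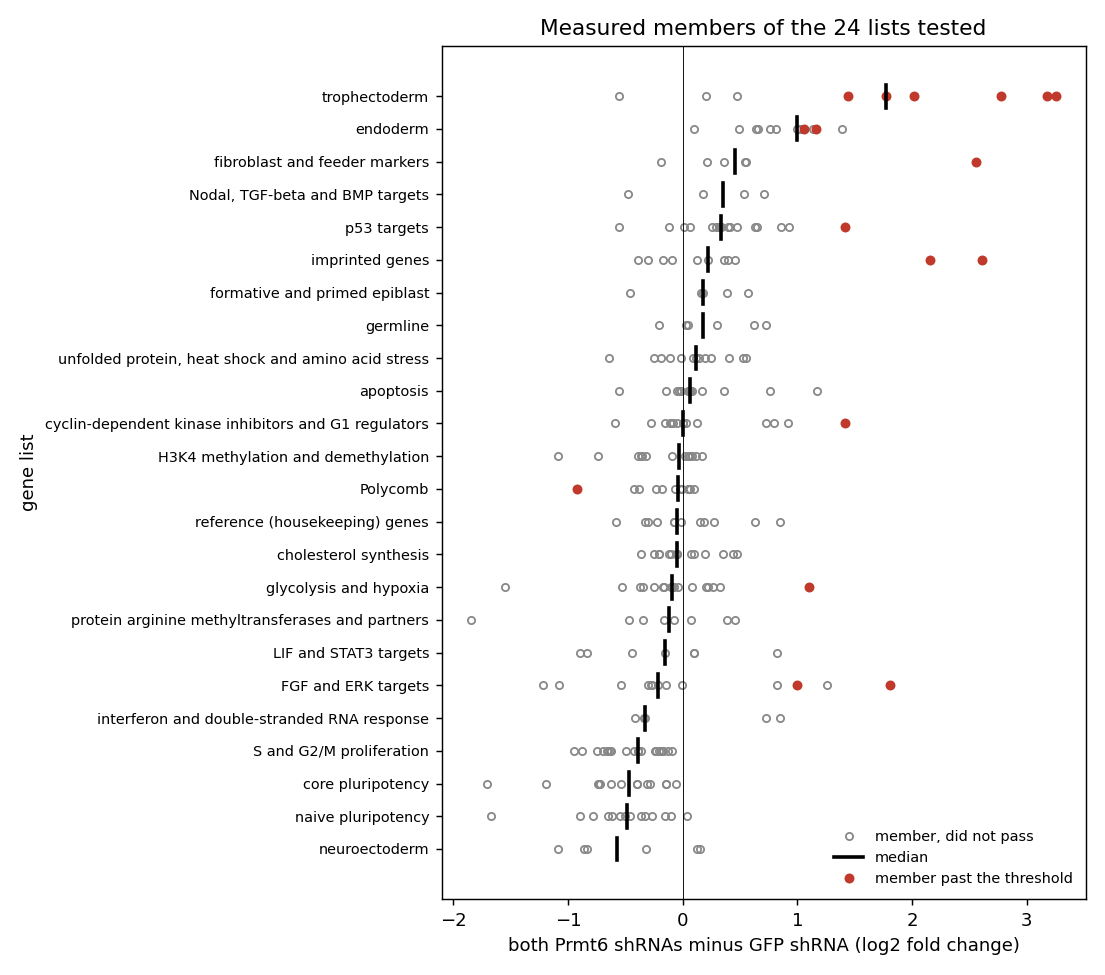
Change with both Prmt6 hairpins against GFP shRNA (horizontal axis, log2 fold change) of the measured members of the 24 lists tested; filled red circles passed the limma threshold, open grey circles did not, and black bars mark medians. Medians ran up to 1.77 for trophectoderm and 1.00 for endoderm, and the medians of the core and naive pluripotency lists were -0.47 and -0.48.

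Prmt6 shRNA1 alone asks what the first hairpin did. Acta1 rose at least 15.8-fold (adjusted p = 0.00219), Krt7 39.5-fold (log2 5.30 ± 0.35, adjusted p = 0.00444), Krt18 20.5-fold (log2 4.36 ± 0.28, adjusted p = 0.00444) and Axl at least 6.35-fold (adjusted p = 0.00219). Tpm2, a muscle tropomyosin, rose 13.3-fold (log2 3.73 ± 0.30, adjusted p = 0.0073). The only falls past the limma threshold were those of Aard at 2.65-fold, Nupr1 at 2.63-fold and Ezh2 at 2.30-fold (log2 -1.40 ± 0.16, -1.40 ± 0.17 and -1.20 ± 0.16; adjusted p = 0.0222, 0.0281 and 0.0361).

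In total 86 genes passed with Prmt6 shRNA1, 83 higher and 3 lower, and 764 had an unadjusted p under 0.05. The count was 16 and 8 without GFP shRNA replicate 1 or 2, 5 and 21 without Prmt6 shRNA1 replicate 1 or 2, and 57 and 51 without Prmt6 shRNA2 replicate 1 or 2. With the first-series probes alone it was 208, with 168 higher and 40 lower. The near absence of falls was not kept there, nor with detection on all 6 arrays (177 higher, 59 lower) or the trend and robust options (247 higher, 63 lower).

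With this hairpin 6 of 9 trophectoderm genes rose, the same number adjusted over the list alone, with a median log2 change of 2.30 (0.63 with 2 members not detected with GFP shRNA at their lower limits, 0.71 without a filter, 1.44 with the authors' values and 3.69 without background correction; camera adjusted p = 1.77e-11, adjusted p = 0.119 with an estimated correlation). Imprinted genes were higher: 2 of 11 rose, Igf2 at 9.56-fold and H19 at least 3.16-fold, 3 adjusted over the list alone, median 0.37, or 0.20 without Prmt6 shRNA1 replicate 1 (adjusted p = 0.00207; adjusted p = 0.222 with an estimated correlation). That call was lost with detection on all 6 arrays (adjusted p = 0.113), and without a filter it was kept at a median of 0.03. Endoderm genes were higher with 0 of 13 past the limma threshold and 6 adjusted over the list alone, median 0.73, or 0.69 with 1 member at its lower limit (adjusted p = 2.15e-06; adjusted p = 0.228 with an estimated correlation). Of the p53 list Cdkn1a rose 2.46-fold, also adjusted over the list alone, and the list was higher with a median of 0.29, which was 0.54 and 0.19 without GFP shRNA replicate 1 or 2 (adjusted p = 0.00181; adjusted p = 0.286 with an estimated correlation). Core and naive pluripotency genes were lower, with 3 and 4 members adjusted over the list alone and medians of -0.44 and -0.39, the latter -0.25 without GFP shRNA replicate 1 (adjusted p = 7.37e-05 and 2.17e-04; adjusted p = 0.181 for each with an estimated correlation). S and G2/M genes were lower with 0 of 22 past the limma threshold adjusted over the list alone and a median of -0.31, or -0.17 without a filter (adjusted p = 7.09e-05; adjusted p = 0.286 with an estimated correlation). Neuroectoderm genes were lower with 3 members adjusted over the list alone and a median of -0.53 (adjusted p = 0.0498; adjusted p = 0.286 with an estimated correlation), a call lost without either GFP shRNA array (adjusted p = 0.0757 and 0.0524) or either Prmt6 shRNA1 array (0.0751 and 0.126). It was also lost with a common median (adjusted p = 0.0645), with the mean of a gene's probes (0.0884), without a filter (0.111, median -0.03), and with the first series alone (0.0514, or 0.0588 without Prmt6 shRNA2 replicate 2 as well). With the authors' values it was kept at a median of -0.32.

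For Prmt6 shRNA2 alone, which asks the same of the second hairpin, Cryab had a rise of 8.16-fold (log2 3.03 ± 0.29, adjusted p = 0.0419) and Anxa3 of 5.44-fold (log2 2.44 ± 0.21, adjusted p = 0.0419). Cemip, a hyaluronan-degrading protein measured by a second-series probe, rose at least 3.80-fold, Pga5, a pepsinogen, at least 3.57-fold, and Gng13, a G protein gamma subunit, at least 2.66-fold (adjusted p = 0.0446, 0.0438 and 0.0438). Eras fell by 1.58 ± 0.22 log2 units (adjusted p = 0.0446). Catsperz fell at least 1.78-fold, Hsd17b11, a lipid droplet dehydrogenase, at least 1.53-fold, Sfrp1 at least 1.16-fold and Ppm1j, a protein phosphatase, at least 1.09-fold (adjusted p from 0.0438 to 0.0446).

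In total 68 genes passed, 61 higher and 7 lower, and 1121 had an unadjusted p under 0.05. The count was 200 with the first-series probes alone, with 145 higher and 55 lower, and 503 without Prmt6 shRNA2 replicate 1, 378 of them lower. With detection on all 6 arrays 278 were higher and 73 lower. By limma the count was 0 without any one of the other 5 arrays, with 585 genes at an unadjusted p under 0.05 without Prmt6 shRNA2 replicate 2, 601 and 646 without GFP shRNA replicate 1 or 2, and 1000 and 1027 without Prmt6 shRNA1 replicate 1 or 2.

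Among endoderm genes Gata4 rose 2.73-fold with Prmt6 shRNA2, 10 of 13 were higher adjusted over the list alone, and the median log2 change was 1.16, or 0.55 without a filter (camera adjusted p = 2.71e-07; adjusted p = 0.240 with an estimated correlation). Trophectoderm genes were higher with 3 risers of 9, 6 adjusted over the list alone and a median of 1.21, which was 0.77 without GFP shRNA replicate 2, and 0.33 with members detected on no GFP shRNA array at their lower limits or at 0, 0.31 without a filter and 0.64 with the authors' values (adjusted p = 4.45e-04; adjusted p = 0.240 with an estimated correlation). Of the p53 list Cdkn1a rose 2.89-fold, 5 were higher adjusted over the list alone, and the median was 0.43, or 0.26 without a filter and 0.27 with the first series alone (adjusted p = 0.00712; adjusted p = 0.288 with an estimated correlation). That call was lost without GFP shRNA replicate 2 or Prmt6 shRNA2 replicate 1 (adjusted p = 0.0854 and 0.162). S and G2/M genes were lower with 3 of 22 adjusted over the list alone and a median of -0.41, or -0.37 with 2 members not detected with Prmt6 shRNA2 at their limits (adjusted p = 5.92e-08; adjusted p = 0.265 with an estimated correlation). Naive and core pluripotency genes were lower with medians of -0.43 and -0.28, the latter -0.53 with the mean of a gene's probes, and 1 and 0 members adjusted over the list alone (adjusted p = 2.31e-05 and 0.00197; adjusted p = 0.240 for each with an estimated correlation).

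The hairpins shared 28 genes that were higher with each, among them Krt8, Krt18, Igf2, H19, Axl, Cryab, Anxa3, Plaur, Cldn4, Phlda1 and Cdkn1a, and none that was lower with each. Shared falls did appear under alternatives, 13 with detection on all 6 arrays, 14 with the trend and robust options, 12 with the first series alone, 15 with the first series on the authors' values, 1 or 2 under 4 others, and 72 at an unadjusted p under 0.05 with each hairpin. Independent lists of these sizes would share 0.774 higher genes and 0.00321 lower. Over 100 simulated sets of unchanged groups that share the control arrays, the mean was 0.01 shared higher genes, but these sets called a mean of only 0.04 and 0.01 higher genes with the hairpins, so this count could not have been large. With the 83 and 61 genes of lowest p among the rises taken from each set instead, a comparison chosen after seeing the data, the simulated sets shared a mean of 19.07 genes, with a range of 10 to 31. The observed 28 lies within that range. The simulation gave every group the same spread for a gene. In the data the SD of the replicate difference was 0.39 log2 units with GFP shRNA, against 0.48 and 0.79 with the Prmt6 hairpins. The simulated sharing through the controls may therefore be too large. Both contrasts also use the same estimate of a gene's spread, so a low estimate favours a gene in both lists. The simulated sharing holds both effects, and it cannot decide whether 28 exceeds what the shared controls and the shared estimate produce. Across genes, which are not independent replicates, the log2 changes with the hairpins correlated with r = 0.474, within the simulated range of 0.439 to 0.550. Their covariance was 0.133, above the simulated range of 0.0676 to 0.0998. The shared count was 26 without Prmt6 shRNA2 replicate 1 and 0 by limma without any one of the other arrays.

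**Figure D4:**
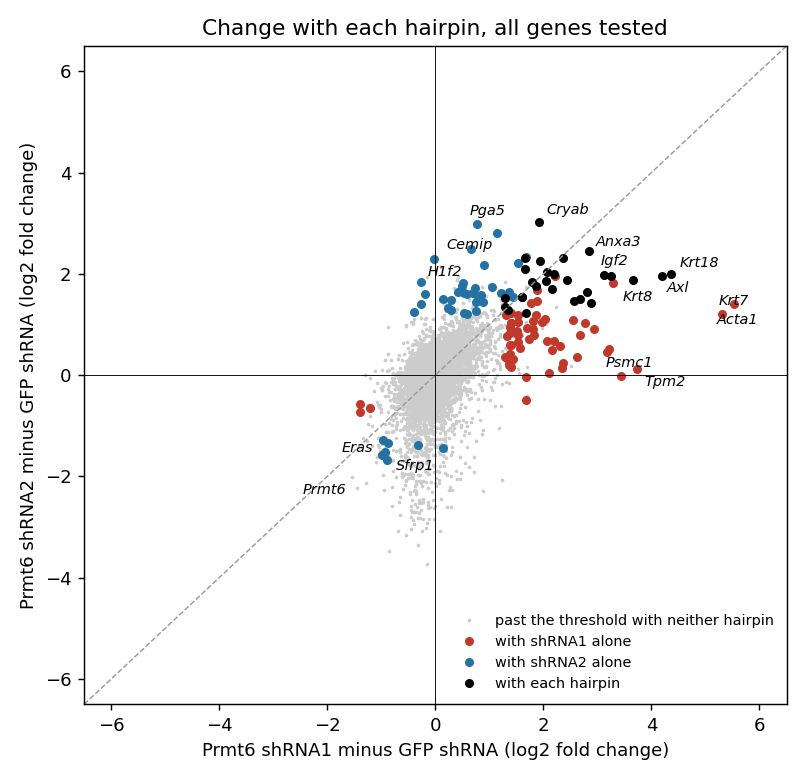
Change with Prmt6 shRNA1 (horizontal axis) and Prmt6 shRNA2 (vertical axis) against GFP shRNA, both as log2 fold change, for all 6539 genes; black points passed the limma threshold with each hairpin, red with shRNA1 alone, blue with shRNA2 alone, and the dashed line marks equal change. The 28 black points lie in the upper right, and Acta1 and Krt7 lie far to the right of the dashed line.

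A direct comparison of Prmt6 shRNA2 with Prmt6 shRNA1 asks where the hairpins differed. With shRNA2, Acta1 was at least 12.6-fold lower (adjusted p = 0.00702), Krt7 lower by a log2 difference of -4.09 ± 0.35 (adjusted p = 0.027) and Tpm2 at least 10.6-fold (adjusted p = 0.027). The probe for Psmc1, a proteasome ATPase gene, was at least 2.33-fold lower (adjusted p = 0.00623), but it was detected only on the 2 Prmt6 shRNA1 arrays, and whether it reports the main transcript of this widely expressed gene was not tested. Also lower was Dmkn, a secreted skin protein, at least 2.03-fold (adjusted p = 0.00804). Higher with shRNA2 were the linker histone H1f2 at 4.33-fold (log2 2.11 ± 0.17, adjusted p = 0.027), the histone H2B genes H2bc4 at 3.18-fold, H2bc13 at 3.12-fold and H2bc22 at 2.84-fold (adjusted p = 0.0358, 0.0358 and 0.0426), and the surface antigen Ly6a at 3.43-fold (adjusted p = 0.0402).

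In total 26 genes differed, 6 higher and 20 lower with Prmt6 shRNA2, and 779 had an unadjusted p under 0.05. The balance was not kept with detection on all 6 arrays (53 higher, 39 lower) or with the trend and robust options (66 higher, 65 lower). The count was 6 and 5 without GFP shRNA replicate 1 or 2, 381 without Prmt6 shRNA2 replicate 1 (32 higher, 349 lower), and 96 with the first-series probes alone. By limma it was 0 without Prmt6 shRNA2 replicate 2 or either Prmt6 shRNA1 array, with 375, 821 and 467 genes at an unadjusted p under 0.05 without Prmt6 shRNA2 replicate 2, Prmt6 shRNA1 replicate 1 and Prmt6 shRNA1 replicate 2.

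Trophectoderm genes were lower with Prmt6 shRNA2 than with shRNA1, with 4 of 9 fallen, 5 adjusted over the list alone and a median log2 difference of -1.72, or -1.10 with 1 member detected with only one hairpin at its limit, -0.38 without a filter and -0.69 with detection on all 6 arrays (camera adjusted p = 3.62e-07; adjusted p = 0.234 with an estimated correlation). Imprinted genes were lower with 3 of 11 adjusted over the list alone and a median of -0.47, or -0.25 with 2 such members at their limits and -0.31 and -0.29 without Prmt6 shRNA1 replicate 1 or 2, -0.14 with detection on all 6 arrays, -0.098 without a filter and -0.24 with the first series on the authors' values (adjusted p = 0.00129; adjusted p = 0.324 with an estimated correlation). Endoderm genes were higher, 0 of them past the limma threshold adjusted over the list alone, with a median of 0.57, or 0.38 without a filter (adjusted p = 0.0109; adjusted p = 0.615 with an estimated correlation). Unfolded protein and stress genes were higher with 3 of 13 adjusted over the list alone and a median of 0.23, which was 0.43 without Prmt6 shRNA2 replicate 1 and 0.048 without replicate 2 (adjusted p = 0.0222; adjusted p = 0.615 with an estimated correlation). Germline genes were higher with 1 of 6 adjusted over the list alone and a median of 0.42 (adjusted p = 0.0242; adjusted p = 0.511 with an estimated correlation). S and G2/M genes were lower with none adjusted over the list alone and a median of -0.14, or -0.083 with 2 members at their limits, -0.072 without a filter and -0.092 with a common median (adjusted p = 0.0258; adjusted p = 0.618 with an estimated correlation). Without Prmt6 shRNA2 replicate 1 the calls of the endoderm, stress, germline and S and G2/M lists were lost (adjusted p = 0.0557, 0.0557, 0.131 and 0.193). The last 3 were also lost without Prmt6 shRNA1 replicate 1 (adjusted p = 0.0918, 0.0981 and 0.189). The processing mattered as well: with detection on all 6 arrays the endoderm and stress calls were lost (adjusted p = 0.195 and 0.236), without a filter the germline call (0.471, median 0.06), and with the authors' values or the mean of a gene's probes the S and G2/M call (0.061 and 0.0569). The stress call was also lost with the first series alone without Prmt6 shRNA2 replicate 2 (adjusted p = 0.0533).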

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

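The contrasts, the lists and the alternatives used here were fixed beforehand, but the tests of explanations were chosen after the result was seen, except the pair that set the probe series of one gene against each other.

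The hairpins differed directly in 26 genes, which is a difference between groups under the same contrast with GFP shRNA. The log2 difference, Prmt6 shRNA2 minus Prmt6 shRNA1, was 2.11 for H1f2, 1.78 for Ly6a, 1.67 for H2bc4, 1.64 for H2bc13 and 1.51 for H2bc22. It was -4.13 for Acta1, -4.09 for Krt7, -3.62 for Tpm2, -3.45 for Psmc1 and -2.73 for Dmkn, of which all but Krt7 are fitted values of genes detected on no Prmt6 shRNA2 array. Of the 26 genes, 0 percent lay on second-series probes, against 17.3% of the genes tested. That share cannot exclude an effect of the low second-series signal of Prmt6 shRNA2 replicate 2. The wide replicate spread on those probes (SD 1.42 log2 units, against 0.42 on first-series probes) made calls there unlikely. With the first-series probes normalized alone, which leaves that signal out, no gene named by the rule and measured there lost its call. A single graded response to the level of Prmt6 would give the larger change to the same hairpin throughout. However, 18 of the 26 genes changed more from GFP shRNA with shRNA1 and 8 with shRNA2, and 15 had both changes of one sign. The Prmt6 level did not differ detectably between the hairpins, so which of them should have the larger change is not known. The split therefore does not set these genes against a measured order of Prmt6 levels. Off-target effects of either hairpin, and differences between the transfected cultures, stay open and were not tested, and the count was 0 by limma when Prmt6 shRNA2 replicate 2 was left out (375 at an unadjusted p under 0.05).

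The difference between the hairpins also showed in 6 lists, each called by camera with the preset correlation and none with an estimated one (adjusted p from 0.234 to 0.618). The median log2 difference was -1.72 for trophectoderm, -0.47 for imprinted genes and -0.14 for S and G2/M proliferation. It was 0.57 for endoderm, 0.42 for germline genes and 0.23 for unfolded protein and related stress. With members detected with only one hairpin at their limits, the first 3 were -1.10, -0.25 and -0.083. Without a filter on dim probes the medians were -0.38, -0.098 and -0.072 for the first 3 and 0.38, 0.065 and 0.16 for the others, and the germline call was lost (adjusted p = 0.471).

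Rises of some keratin, actin and tropomyosin genes were among the largest in the main comparison, and 8 such genes passed. They were grouped after their values were seen, and no test of these families as a set was run. Actb (log2 0.28, limma adjusted p = 0.449) and Tpm3 (-0.23, limma adjusted p = 0.629) did not pass. Tpm2 was at 3.73 with Prmt6 shRNA1 and 0.12 with Prmt6 shRNA2. Fibroblasts or feeder cells among the Prmt6 shRNA cells would bring their abundant collagens: of 18 fibroblast markers not detected with GFP shRNA, 0 were detected on 2 or more Prmt6 shRNA arrays, with Col1a1, Col1a2 and Col3a1 detected on none. The mean intensity of Vim, which these cells also express, was 3537 with GFP shRNA, 3527 with Prmt6 shRNA1 and 3908 with Prmt6 shRNA2. Quantile normalization does not account for the rise, since all 8 genes stayed past the threshold with a common median. The 7 of them detected with GFP shRNA had log2 changes of 1.42 to 3.21 there, against 1.36 to 3.26 in the main comparison. A change of cell state after loss of Prmt6 may be a reason, but it was not tested, and off-target effects of the hairpins and differences between cultures stay open as well.

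The second-series probes gave low signal on Prmt6 shRNA2 replicate 2. In 472 genes with a kept probe in each series, the change from replicate 1 to replicate 2 of that group was lower on the second-series probe by a median of -0.495 log2 units (SD 1.47), just short of the -0.5 set beforehand as the sign of an array fault. The same median was 0.274 with GFP shRNA and 0.181 with Prmt6 shRNA1. The second-series probe was lower by over 1 log2 unit in 166 of these genes, against 14 for the first series, 4 against 11 with GFP shRNA and 12 against 7 with Prmt6 shRNA1. In those 166 genes the first-series probe had a median change of 0.105 (SD 0.390), above the -0.5 that lower transcript levels in the sample would need. These values argue against lower transcript levels as the explanation in those 166 genes. A low signal on part of the array remains a candidate explanation. The value set beforehand for it was narrowly missed, and what lowered the signal was not tested.

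Among the 968 kept probes without a matched symbol, which the comparisons do not use, 1 passed with Prmt6 shRNA1, at least 3.31-fold higher (limma adjusted p = 0.0344 among these probes). It was detected on both Prmt6 shRNA1 arrays and on no other array.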

How the results depend on the processing

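The tests with the first probe series alone, with separate normalization of the series, with array weights and with their combinations were chosen after the result was seen; the others were fixed beforehand. No gene named by the rule, no gene called against GFP shRNA and no called list reversed its direction under any alternative that gave a value. Named genes that were neither were not checked in this way. Of the 26 genes that differed between the hairpins, 1 changed sign without a filter. Without Prmt6 shRNA2 replicate 1, a fit that leaves 1 array in that group, the balance of calls turned towards falls with both hairpins and with Prmt6 shRNA2. Counts are given in the order Prmt6 shRNA1, Prmt6 shRNA2, both hairpins, the direct difference, and genes called with both hairpins; as reported they were 86, 68, 109, 26 and 28, and the cause of a moved count was not tested unless stated. A threshold of at least 1.5-fold, applied to fitted values and not to lower limits, left every count as it was. The mean of a gene's probes kept each count within 1.5 times.

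Without background correction the counts were 39, 0, 23, 1 and 0; without a filter, with 20497 genes tested, 37, 0, 26, 7 and 0; and with every probe tested, 48, 0, 29, 3 and 0. A fit to only the groups compared gave 57, 0, 20, 5 and 0, and the replicate number as a block gave 6, 0, 0, 0 and 0, though replicate numbers did not pair the samples. Deviations of same-numbered arrays correlated with r = -0.648 for GFP shRNA and Prmt6 shRNA1. For GFP shRNA and Prmt6 shRNA2 r was 0.124, and for the Prmt6 hairpins -0.359. Where r is negative, arrays of unlike number deviated alike, and a factor shared across groups in that way was not modelled. The limma counts of 0 with Prmt6 shRNA2 had 1074, 1769, 1132, 1010 and 785 genes at an unadjusted p under 0.05, and those of the block 683 and 510 for both hairpins and the difference. A common median gave 139, 190 and 52 for Prmt6 shRNA2, both hairpins and the overlap, with the median of all genes at 0.13 with Prmt6 shRNA2, as with detection on all 6 arrays (0.16 without Prmt6 shRNA2 replicate 1). An offset of 50 gave 107 for Prmt6 shRNA2. The authors' values gave 143, 195, 40 and 49 for all but the first hairpin. Detection on all 6 arrays, with 4099 genes tested, gave 236, 351, 302, 92 and 126. The trend and robust options gave 310, 430, 400, 131 and 153, and an adjusted p under 0.10 gave 149, 179, 260 and 58 for all but the difference. At an unadjusted p under 0.05 with each hairpin, 401 genes were shared.

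The first series alone gave 208, 200, 273, 96 and 82, and with the authors' values 316, 529, 422, 179 and 152. Separate normalization moved Prmt6 shRNA2 to 34; array weights moved both hairpins to 188 and the difference to 3. The first series without Prmt6 shRNA2 replicate 2 gave 0 for Prmt6 shRNA2 by limma (600 at an unadjusted p under 0.05), 37 for both hairpins, 3 for the difference and 0 for the overlap.

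Leaving out each array in turn gave 5 to 57, 0 to 503, 0 to 460, 0 to 381 and 0 to 26, with the lone array of a group assumed to vary like the others. Of the genes called, 5 of 86, 0 of 68, 0 of 109 and 0 of 26 kept their call throughout, and 22, 0, 24 and 5 in at least 3 of these fits. Of 83 values of single named genes, 71 lost their call with the replicate block, 57 without background correction, 53 with only the groups compared, 47 without a filter, 46 with every probe, and 2 to 64 as arrays were left out. The highest counts came without Prmt6 shRNA2 replicate 1, which leaves the array with low second-series signal alone in its group.

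Prmt6 passed at fitted values of -1.67 with a common median, -1.49 with an offset of 50, and -1.84 with trend and robust options, array weights or an adjusted p under 0.10. It ranged from -2.08 to -1.65 as arrays were left out and from -3.37 to -1.12 over all alternatives, with adjusted p from 0.013 to 0.49. No value could be had for Prmt6 from the first series or with detection on all 6 arrays. Between 6 and 9 lists were called by camera under the alternatives that keep its preset correlation, against 7 as reported, and 0 with an estimated correlation. The list tests were not rerun for every probe, only the groups compared, 1.5-fold or array weights, and a slide block was not run. Signal over background limits all of this: 44.5% to 57.6% of the intensities of an array lay below 0.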

Other observations

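The lists and the tests of groups in this part were chosen after the result was seen, and the genes named here after their values were seen.

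Besides the keratins, the genes past the threshold on the average of both Prmt6 hairpins included genes of the contractile and cortical cytoskeleton. Some of these were detected on no Prmt6 shRNA2 array (Acta1, Tpm2, Myl9 and Anxa1). Of 30 measured targets of serum response factor (SRF) and its actin-regulated cofactor MRTF, 12 rose and 18 did not pass, with 26 above 0 and a median log2 change of 0.66, or 25 and 0.62 with 3 members not detected with GFP shRNA at their limits, or at 0 where none lay above 1-fold. Tpm1, a tropomyosin, rose 4.25-fold (limma adjusted p = 0.0104), Flnc, an actin crosslinker, 3.79-fold (adjusted p = 0.0274) and Zyx, a focal adhesion protein, at log2 1.26 (adjusted p = 0.0424). Of 5 measured annexins 4 rose, among them Anxa2 at 3.51-fold (adjusted p = 0.0116) and Anxa5 at 2.24-fold (adjusted p = 0.0376). Of 21 lamin, plakin and junction genes 7 rose, including Ahnak at 4.44-fold, Lmna, which encodes lamin A and C, at 2.98-fold, and Plec, a cytoskeletal linker, at 2.74-fold (adjusted p = 0.0101, 0.0274 and 0.0212). Of 12 measured targets of YAP and TEAD 4 rose, among them Ccn1, a matricellular protein, at least 2.03-fold (adjusted p = 0.0376). Of these 12, 10 lay above 0, and Tead1 (log2 -1.16 ± 1.09) and Wwc1 (-0.20) lay below. These lists also held members undetected on one side of the comparison. With those at their limits or at 0, the annexin median moved from 1.25 to 1.17, with 3 of 5 above 0. That of lamin, plakin and junction genes moved from 0.86 to 0.38, with 14 of 21 above 0. For YAP and TEAD targets it moved from 1.05 to 0.79, with 10 of 12 above 0. Egr1 (-1.08) and Fos (-0.30) were among the SRF and MRTF targets below 0. Some rises came mainly from Prmt6 shRNA1: Flnc was at log2 2.93 with it and 0.91 with Prmt6 shRNA2, and Tpm2 at 3.73 and 0.12. Others did not, such as Zyx at 1.36 and 1.15 and Ccn1 at 1.53 and 2.22, in the same order.

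Whether each group is higher as a whole was asked of the members that were not called, since the lists were written after called members were seen. SRF or YAP activity may be higher in these cells, but the camera tests with an estimated correlation do not settle it: the adjusted p over 5 lists was 0.206 for SRF and MRTF targets, 0.259 for YAP and TEAD targets, 0.206 for annexins and 0.377 for lamin, plakin and junction genes. Of the measured members, 5, 1, 0 and 2 also belonged to lists fixed beforehand.

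In the direct comparison of the hairpins, 4 of 33 measured replication-dependent histone genes were higher with Prmt6 shRNA2, 27 lay above 0 (24 with 3 members that a hairpin's arrays did not detect set at 0), and the median log2 difference was 0.78. A rise of such genes as a group was not settled by the members that were not called (adjusted p = 0.191 with an estimated correlation), and signal shared between similar histone probes was not tested.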
